A study of Homo sapiens with 4 samples.

How the data were processed

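Poly(A) RNA of primary human epidermal keratinocytes was converted to strand-preserving libraries, per the labels' protocols, with 2 libraries of undifferentiated progenitors and 2 of cultures treated for 48 h with 1.22 mM calcium chloride. STAR 2.6.1, DESeq2 without a version and the genome build hg19 are named in the submitters' processing notes, which give no role or order. The read counter, its strand setting, the annotation and the handling of replicates are not given in the sources used here, so reads of overlapping or near-identical genes cannot be assigned with certainty.

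The data analysed here were 1 table of the authors' own comparison. Its mean column is a signal per gene, the authors' mean over the 4 libraries of counts divided by size factors, per the file headers. Log2 fold changes and their log2 standard errors were computed by the authors, per the file headers. A further column is the authors' Wald statistic, a score equal to the fold change divided by its standard error, which was checked on the table (largest difference 6.94e-08). The deposited p-values and adjusted p-values are the authors' DESeq2 output per the file headers, and the adjusted values were recomputed by Benjamini-Hochberg over the 12726 genes with an adjusted p (largest difference 8.1e-07). The smallest mean count with an adjusted p was 10.02, and 5238 genes with lower counts had a p and no adjusted p. A further 8400 genes were listed at a mean of 0. The standard errors have a ceiling of 0.75 on the log2 scale, which 789 genes approached within 1%. That is what a normal prior of SD 1.50 on the fold change gives, so the deposited fold changes were read as moderated towards 0, although no label or header states it. Moderation leaves the Wald statistic nearly as it was and understates folds of low or variable genes. Of the symbols, 28 had been turned into dates, of which 17 had an adjusted p and 2 were called, and 2 symbols were listed more than once. These were counted as genes and not named.

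No column holds values per library, so no count model was fitted here and the main result is the adjusted p deposited by the authors from DESeq2, at a threshold of 0.05. Depth was read from low counts. Among 1679 genes with a mean count of 0.35 to 1.4, 100% were sums of whole reads in 4 steps (tolerance 1e-05), against 0.119% of shifted values. The steps correspond to size factors of 1.18 and 1.07 for libraries on the side of positive fold changes and 0.95 and 0.84 for those on the negative side, a ratio of mean size factors of 1.26. Totals of each library were not recovered. Precision was set by depth and spread together. Genes with mean counts of 100 to 200 had a median standard error of 0.40, and the smallest log2 fold change called among them was 0.98 in size. Larger changes at such counts were not always called, so this is no detection limit.

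The sign of the fold change is not stated by a label. It was read as differentiated over undifferentiated because KRT1 and KRT10 were positive and MKI67 negative, and IVL was positive and not called. The call threshold, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. That rule took the 12 highest and the 12 lowest log2 fold changes among called genes with a mean count of at least 100, up to 3 called members per direction of each list with a mean count of at least 10, and, whatever their values, IVL, LOR, FLG, KRT1, KRT10, KRT5, KRT14, COL17A1, ITGB4, MKI67, TP63, KLF4, GRHL3, ZNF750, OVOL1, PRDM1, MAF, CEBPA, KDM1A and RCOR1. Together it named 132 genes, of which some are not reported here. COL1A1, COL1A2, FAP and the genes named in the closing section that this rule did not pick were chosen after their values were seen. Some of these, such as FN1, SLPI, SBSN and CD68, are members of the fixed lists.

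Lists were matched by symbol, and members with an adjusted p and a mean count of at least 10 counted as measured. Lists with at least 5 such members, 26 of 29, were tested on the Wald statistics with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Enrichment among calls was tested with one-sided Fisher's exact tests in scipy 1.17.1 against all genes with an adjusted p, adjusted over lists and directions. Each list median was also compared with 10000 random lists matched on mean count. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

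Alternatives covered the threshold, the size of change, a null of 1.5-fold or less, count filters, Bonferroni and Benjamini-Yekutieli adjustment, re-centring, an empirical null, correlations of 0.05 and 0.1, ranks, fold changes in place of Wald statistics, and further shrinkage. Fold changes with the prior undone, and a correction for transcript length and GC content, were added after the data were seen. A reference of another build than the authors' served for transcript length, GC content and shared 31-base words alone, matched 95.2% of the genes with an adjusted p, and gave no coordinates.

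The procedures were tested on simulated data for the comparison of differentiated and undifferentiated cultures with 12726 genes. Of 100 genes changed by a log2 fold change of 1, 24% were recovered, and of 100 changed by 2, 84%. Unchanged genes made up 6.9% of calls. All other simulated genes were unchanged, with independent noise scaled by the deposited standard errors. The data had far more calls (1988) and a wider spread of Wald statistics (1.57), so these rates need not hold for them. The list test called 2 of 2 shifted lists and 0 of 23 unshifted ones. Its simulated genes were independent, so this does not show how often lists of correlated genes are called falsely.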

Results

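RNA was sequenced from primary human epidermal keratinocytes, the cells that build the outer layer of the skin, in 2 states. There were 2 libraries of undifferentiated, proliferating progenitors and 2 libraries of cultures kept for 48 h with 1.22 mM calcium chloride, which makes keratinocytes stop dividing and differentiate. The series title places this comparison within work on LSD1, the histone demethylase encoded by KDM1A, and on transcription factors of epidermal fate. The comparison asks which genes differ between the proliferating and the differentiated state. The labels do not say whether the libraries of a group came from separate cultures or donors, so each p-value measures only the spread between these libraries, which may be technical. Each number in the sample titles occurs in both groups, and no label says whether it marks a shared culture, donor or batch, so the libraries may be paired in a way that the deposited standard errors do or do not take up. The authors' deposited table gives, for each of 26364 gene symbols, the mean normalised read count over the 4 libraries, the log2 fold change with its standard error, and DESeq2 p-values. It was the only file analysed here, so no value per library is reported. Mean normalised counts in the authors' deposited table summed to 8.28e+06 reads per library. The steps that 1 read makes in low counts corresponded to size factors of 1.18, 1.07, 0.95 and 0.84. The fold changes were read as moderated towards 0, and undoing that prior, an alternative chosen after the data were seen, moved the fold of 30 of the 159 named genes with an adjusted p by over 1.5 times. For IVL, KRT1, MKI67, ID4 and ATF3 below, the standard error lay near the ceiling of 0.75. There the undone value is poorly determined and is given as a rough guide only. A positive log2 fold change was read as higher in the differentiated cultures. That direction was judged from the markers KRT1, KRT10 and MKI67 in the table, so the direction of the lists that hold these markers is not independent evidence of the sign.

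Calcium-treated cultures carried much more RNA for proteins of the outer epidermis and much less for proteins of DNA replication and mitosis. Among genes with a mean normalised count of at least 100, UNC5B, a netrin receptor, had in the authors' deposited table a log2 fold change of 5.62 (standard error 0.33), which is 49.3-fold, with a DESeq2 adjusted p of 4.38e-62. GDF15, a stress-induced secreted factor, was 84.2-fold higher (standard error 0.59 on the log2 scale; log2 fold change 7.87 with the prior undone), the highest of the 12 genes named by the largest increase in the authors' deposited table. The others were NOTCH3 (5.53), the cornified envelope gene SPRR2D (5.44), LCN2 (5.35), TMEM45B (5.30), the protease inhibitor gene SPINK5 (5.12), MUC1 (4.88), TGM1 (4.81), S100A9 (4.81), GPR1 (4.79) and SULT2B1 (4.54), all as log2 fold changes in the authors' deposited table. At the other end of the authors' deposited table, MYBL2, a transcription factor of cycling cells, had the lowest value, with a log2 fold change of -4.87 (standard error 0.39), 29.3-fold lower. Below -4 on the log2 scale in the authors' deposited table were also RRM2 (-4.72), which encodes a subunit of ribonucleotide reductase, KIF18B (-4.45), EXO1 (-4.43), ANLN (-4.37), HJURP (-4.34), TGM2 (-4.33), FAM111B (-4.31), THBS1 (-4.23), CLSPN (-4.22), BRIP1 (-4.21) and DLGAP5 (-4.16). TGM2 and THBS1 encode a protein cross-linking enzyme and a matrix glycoprotein, and most of the others act in DNA replication, DNA repair or mitosis. SPRR2D and RRM2 share 37.1% and 33.1% of their 31-base words with transcripts of other genes, so part of their reads is uncertain.

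Of the 12726 genes with an adjusted p in the authors' deposited table, 1988 were called at a DESeq2 adjusted p under 0.05, which is 15.6%. In the differentiated cultures 902 of the called genes rose and 1086 fell. Re-centring the fold changes on the 1640 genes with a mean count of at least 1000, whose median was -0.13 on the log2 scale, gave 1162 higher and 893 lower. The share of higher calls was 56.5% on that scale and 45.4% as deposited, so the balance of rises and falls depended on the scaling.

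Measured genes of the late epidermal programme mostly rose. The cornified envelope and late differentiation list, which builds the dead protective layer of the skin, had 23 measured genes of 54 listed. Of these 23 genes, 16 rose and none fell, 20 and 0 when adjusted over the list alone. The other listed genes had counts too low to be measured, except 1 that was absent from the authors' deposited table. The result therefore does not cover the listed genes that were not measured. The list median was a log2 fold change of 1.74 (cameraPR adjusted p = 9.83e-20). SPRR2D, the cross-linking enzyme gene TGM1 and KRTDAP stood at 5.44, 4.81 and 4.06 in the authors' deposited table, and the filaggrin gene FLG at 2.22 (standard error 0.69, DESeq2 adjusted p = 0.012), or 3.23 with the prior undone. Involucrin, IVL, had a log2 fold change of 1.60 (standard error 0.75), or 3.21 with the prior undone, and was not called (DESeq2 adjusted p = 0.145 in the authors' deposited table). Its standard error lay at the ceiling, where the undone value is poorly determined. Loricrin, LOR, a late marker, had a mean normalised count of 0.423 and no adjusted p in the authors' deposited table, so a change was not detectable at this depth. Suprabasal keratins and desmosomal genes rose in 12 of 19 measured members with none falling, 12 and 1 when adjusted over the list alone (median 1.11, cameraPR adjusted p = 9.44e-08). Here the desmosomal cadherin gene DSG1 reached 3.90, KRT13 3.27 on the log2 scale of the authors' deposited table, while KRT1 stood at 2.13 (DESeq2 adjusted p = 0.0267), or 3.53 with the prior undone, and KRT10 at 1.47 (0.00102). KRT1 was a minor transcript, with a mean normalised count of 17 against 204.8 for KRT10 in the authors' deposited table.

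Secreted proteases, their inhibitors and barrier lipid enzymes followed the same direction. Kallikreins and protease inhibitors, which control shedding of the surface layer, rose in 18 of 29 measured members and fell in 1, 19 and 2 when adjusted over the list alone (median 1.4, cameraPR adjusted p = 5.05e-15). SPINK5 (5.12), TMPRSS4 (3.73) and WFDC5 (3.59) led in the authors' deposited table, and the protease gene ST14 was the member that fell (-0.80, DESeq2 adjusted p = 0.0421). Epidermal lipid barrier genes rose in 12 of 33 and fell in 2, 14 and 3 when adjusted over the list alone (median 0.69, cameraPR adjusted p = 1.81e-07). Among them were SULT2B1, which makes cholesterol sulfate, at 4.54, the lipoxygenase gene ALOX12B at 4.29 and PLA2G4F at 3.89 in the authors' deposited table, whereas ELOVL6 and PNPLA3 fell, at -1.06 and -1.25. Cholesterol synthesis moved the other way, with 12 of 24 genes lower and 1 higher, 18 and 1 when adjusted over the list alone (median -0.87, cameraPR adjusted p = 6.26e-07). INSIG1 (-1.76), HMGCS1 (-1.62) and EBP (-1.58) fell, and TM7SF2 rose (1.08), in the authors' deposited table.

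**Figure D1:**
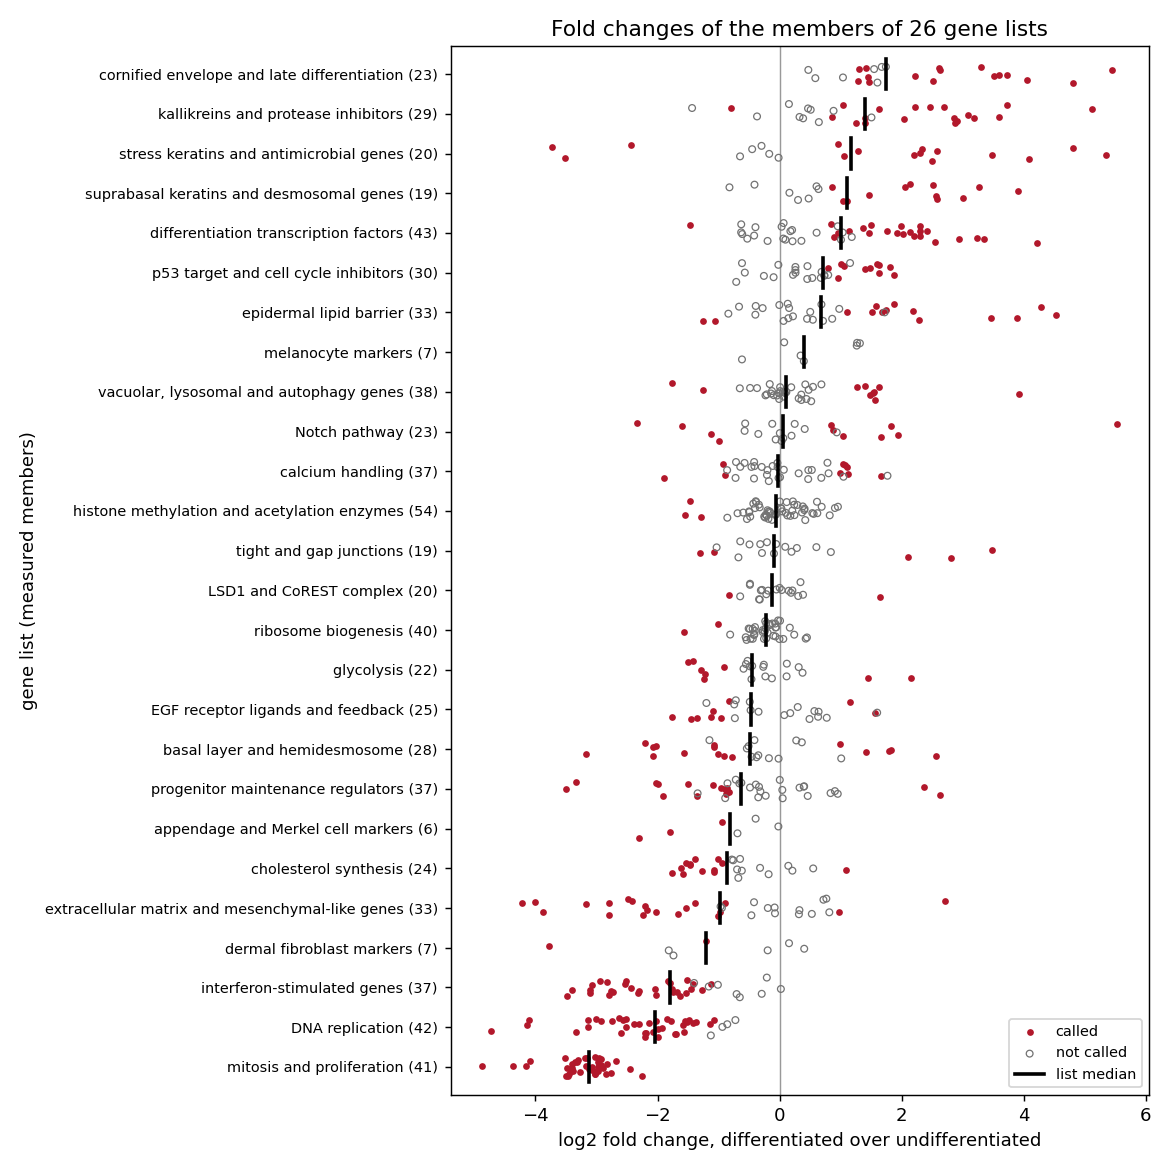
Log2 fold changes (x axis, differentiated over undifferentiated, log2 scale) of the measured members of the 26 tested gene lists (y axis, number of measured members in brackets). Filled red points are genes called at a DESeq2 adjusted p under 0.05 in the authors' deposited table, open points were not called, and black bars are list medians. Medians run from -3.12 for mitosis and proliferation to 1.74 for the cornified envelope list.

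Every one of the 41 measured mitosis and proliferation genes fell, also when adjusted over the list alone, with a list median of -3.12 (cameraPR adjusted p = 9.43e-91). MYBL2, ANLN and DLGAP5 were described above, and MKI67, the antigen used to score cycling cells, stood at -3.17 in the authors' deposited table with a wide standard error of 0.71 (DESeq2 adjusted p = 0.000144), or at -4.83 with the prior undone. DNA replication genes fell in 38 of 42, and in 41 when adjusted over the list alone, with none rising (median -2.05, cameraPR adjusted p = 1.16e-41). MCM10 (-4.14), a replication initiation factor, and TK1 (-4.11), thymidine kinase, were near the head of that list in the authors' deposited table. The p53 target and cell cycle inhibitor list rose in 11 of 30 members with none falling, 13 and 0 when adjusted over the list alone (median 0.71, cameraPR adjusted p = 2.10e-05). CDKN1C (1.87) and CDKN2B (1.81), which encode inhibitors of cyclin-dependent kinases, and the antiproliferative gene BTG2 (1.63) were its highest called members in the authors' deposited table. Replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails and are poorly captured by poly(A) selection, had 1 measured member of 32 listed, HIST1H1C, which rose (1.67, standard error 0.50 in the authors' deposited table), also when adjusted over the list alone, and the list was not tested.

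Basal layer genes moved in both directions. The basal keratins KRT5 (-0.41, DESeq2 adjusted p = 0.368) and KRT14 (-0.46, 0.353) and the hemidesmosomal collagen gene COL17A1 (-0.35, 0.479) were not called in the authors' deposited table. KRT14 shares 46.1% of its 31-base words with transcripts of other genes, so its count is uncertain. The integrin genes ITGB6 (-3.18), ITGA2 (-2.08) and ITGB4, which encodes the hemidesmosome integrin, fell, the last at -1.08 (DESeq2 adjusted p = 0.00125 in the authors' deposited table), as did the basement membrane collagen gene COL4A1 (-2.21). ASS1 (2.56), SYT8 (1.83) and DST (1.80), which encodes a hemidesmosomal linker protein, rose in the authors' deposited table. Over the basal layer and hemidesmosome list 11 of 28 genes fell and 5 rose, 12 and 6 when adjusted over the list alone (median -0.48, cameraPR adjusted p = 0.00475). At a preset correlation of 0.1 the list was no longer called (cameraPR adjusted p = 0.125).

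Extracellular matrix and mesenchymal-like genes fell in 18 of 33 and rose in 2, 19 and 3 when adjusted over the list alone (median -0.98, cameraPR adjusted p = 3.94e-13). THBS1 (-4.23), the gelatinase gene MMP9 (-4.01) and the activin subunit gene INHBA (-3.87) fell, and the proteoglycan gene BGN (2.71) and the metalloproteinase inhibitor gene TIMP3 (0.97) rose, in the authors' deposited table. Dermal fibroblast markers moved with this list, with 2 of 7 measured members lower and none higher, 4 and 0 when adjusted over the list alone (median -1.20, cameraPR adjusted p = 0.00794). THY1 stood at -3.77 with a mean normalised count of 215.5, and MFAP5 at -1.20, in the authors' deposited table. COL1A1, the collagen gene that fibroblasts express most strongly and that was chosen here after its value was seen, had a log2 fold change of 0.15 and a mean normalised count of 127 in the authors' deposited table. FAP (-1.82) and COL1A2 (-1.74), also chosen after their values were seen, had low mean normalised counts of 15.1 and 11.4. Neither was called over all genes (DESeq2 adjusted p = 0.0574 and 0.0909 in the authors' deposited table). Of the 7 measured members, 5 had negative and 2 positive fold changes. Appendage and Merkel cell markers fell in 3 of 6, also when adjusted over the list alone (median -0.82, cameraPR adjusted p = 0.00501), through the simple-epithelium keratin gene KRT7 (-2.31), KRT75 (-1.79) and KRT19 (-0.95) of the authors' deposited table.

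Of 14 melanocyte markers 7 were measured and none was called, also when adjusted over the list alone (median 0.40, cameraPR adjusted p = 0.275). Immune and Langerhans cell markers had 2 measured members of 16 listed, neither called over all genes or adjusted over the list alone, and none of the 10 endothelial markers reached a mean normalised count of 10.

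Transcription factors of epidermal differentiation rose in 22 of 43 measured members and fell in 1, 24 and 1 when adjusted over the list alone (median 1.01, cameraPR adjusted p = 2.73e-08). ZNF750, a direct activator of late epidermal genes, stood at 4.22 (standard error 0.48), CEBPA at 3.35 and GRHL3, a regulator of barrier formation, at 3.23 in the authors' deposited table. KLF4 (2.30, DESeq2 adjusted p = 1.49e-07) and OVOL1 (2.13, 0.00171) rose too in the authors' deposited table, and the AP-1 gene FOSL1 fell (-1.47). MAF (1.03, DESeq2 adjusted p = 0.102), PRDM1 (0.07, 0.944) and TP63, the master regulator of the epidermal lineage (0.40, 0.414), were not called in the authors' deposited table. Their standard errors in the authors' deposited table were 0.44 for MAF, 0.35 for PRDM1 and 0.28 for TP63.

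Regulators that keep progenitors in their state fell in 13 of 37 and rose in 2, 15 and 3 when adjusted over the list alone (median -0.63, cameraPR adjusted p = 0.000454), although 10 members also belong to other lists. FOXM1 (-3.50), which drives mitotic genes, UHRF1 (-3.33), which recruits DNA methylation at replication, and SOX9 (-2.03) fell in the authors' deposited table. ID4 rose (2.63, standard error 0.75), or 4.92 with the prior undone, at a mean normalised count of only 10.6 in the authors' deposited table. With a preset correlation of 0.1 the cameraPR adjusted p of this list was 0.0776. Few genes of the LSD1 and CoREST complex passed the test, with 1 of 20 higher and 1 lower, 1 and 0 when adjusted over the list alone (median -0.12, cameraPR adjusted p = 0.814). KDM1A had a log2 fold change of -0.65 (standard error 0.30, DESeq2 adjusted p = 0.133) and its partner RCOR1 0.34 (standard error 0.30, 0.544) in the authors' deposited table. GSE1 rose (1.65, DESeq2 adjusted p = 2.5e-05) and the deacetylase gene HDAC1 fell (-0.82, 0.0358) in the authors' deposited table. Histone methylation and acetylation enzymes fell in 3 of 54 and rose in none, 2 and 0 when adjusted over the list alone (median -0.07, cameraPR adjusted p = 0.814), and both this median and that of the LSD1 list were above 0 after re-centring on genes with a mean count of at least 1000. The 3 were SUV39H1 (-1.55) and SUV39H2 (-1.28), which methylate histone H3 lysine 9, and WHSC1 (-1.47) in the authors' deposited table.

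**Figure D2:**
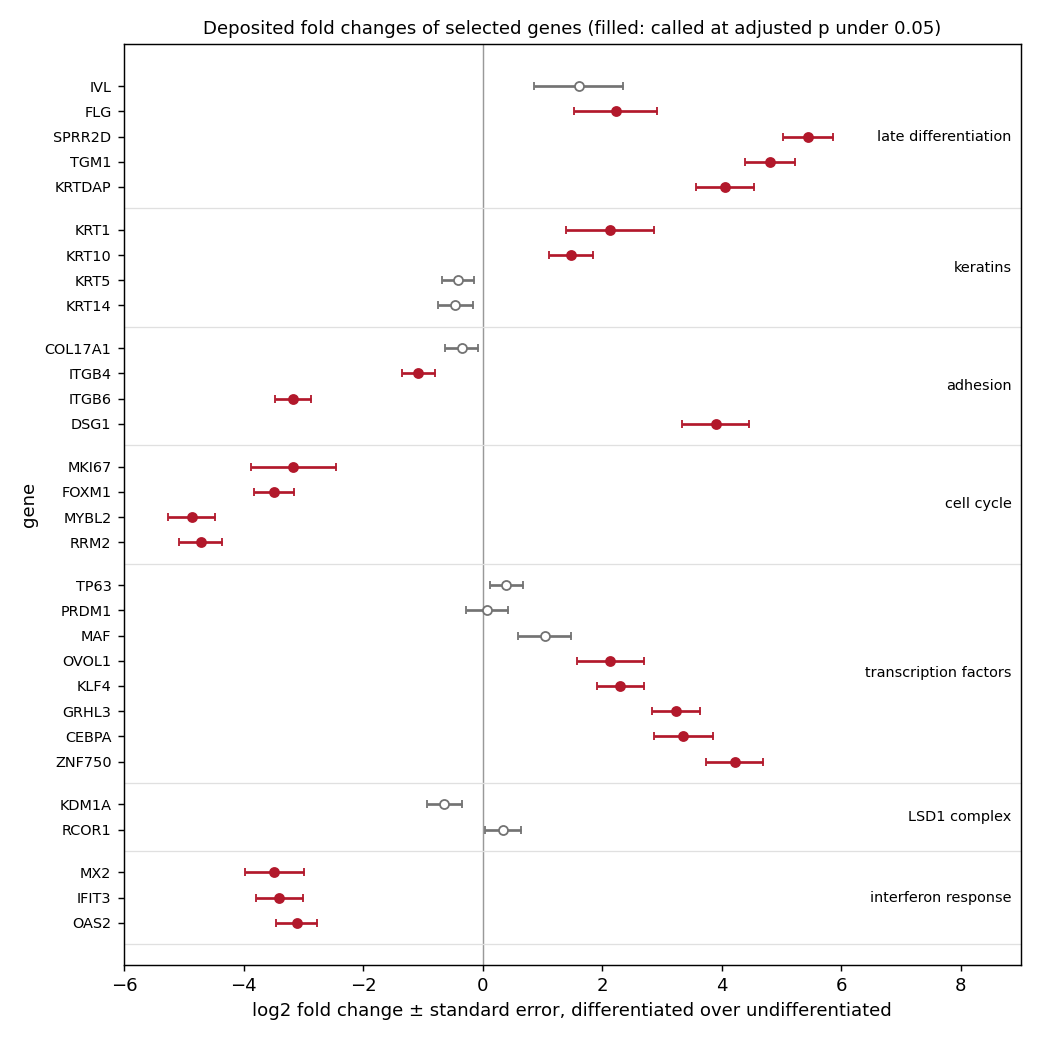
Log2 fold changes with standard errors (x axis, differentiated over undifferentiated, log2 scale) of selected genes (y axis) in the authors' deposited table, where filled red points were called at a DESeq2 adjusted p under 0.05 and open points were not. ZNF750 (4.22) lies far above 0, whereas KDM1A (-0.65), TP63 (0.40) and KRT5 (-0.41) were not called.

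Interferon-stimulated genes, which encode antiviral proteins, fell in 29 of 37 members and rose in none, 31 and 0 when adjusted over the list alone (median -1.80, cameraPR adjusted p = 1.32e-28). MX2 (-3.49), IFIT3 (-3.40) and OAS2 (-3.11) stood lowest in the authors' deposited table. Stress keratins and antimicrobial genes rose in 12 of 20 and fell in 3, 12 and 4 when adjusted over the list alone (median 1.18, cameraPR adjusted p = 2.77e-06). LCN2, S100A9 and S100A8 (4.08), whose products bind siderophores or metal ions, rose, and the cytokine genes CXCL1 (-3.74), IL24 (-3.51) and CXCL5 (-2.44) fell, in the authors' deposited table. Other cytokine genes of this list rose or were not called.

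Signalling lists were mixed. Notch pathway genes rose in 7 of 23 and fell in 4, 8 and 4 when adjusted over the list alone, and the list did not move one way (median 0.06, cameraPR adjusted p = 0.185). NOTCH3 (5.53, standard error 0.40), MAML3 (1.94) and NRARP (1.83) rose and MAML2 (-2.33), DTX3L (-1.59) and DLL1 (-1.12) fell in the authors' deposited table. EGF receptor ligands and feedback genes fell in 7 of 25 and rose in 2, 10 and 4 when adjusted over the list alone (median -0.47, cameraPR adjusted p = 0.221). The feedback phosphatase gene DUSP4 (-1.77), ETV4 (-1.46) and SPRY4 (-1.35) fell, and the ligand gene EPGN (1.56) and EGR1 (1.16) rose, in the authors' deposited table. Calcium handling genes rose in 6 of 37 and fell in 3, also when adjusted over the list alone, with a median of -0.03, a mean of 0.11 and a cameraPR adjusted p of 0.672. PLCD1 (1.67), ORAI3 (1.12), a subunit of store-operated channels, and CAMK2D (1.10) rose while S100A2 (-1.90), S100A10 (-0.93) and CALM2 (-0.89) fell in the authors' deposited table. Tight and gap junction genes rose in 3 of 19 and fell in 2, also when adjusted over the list alone, with a median of -0.09, a mean of 0.22 and a cameraPR adjusted p of 0.355. The medians of the calcium and junction lists were above 0 after re-centring on genes with a mean count of at least 1000. The claudin genes CLDN1 (3.48) and CLDN7 (2.11) and the occludin gene OCLN (2.82) rose, and the gap junction gene GJB2 (-1.07) fell, in the authors' deposited table. ORAI3 shares 51.5% of its 31-base words with transcripts of other genes in the reference annotation, which holds overlapping gene models, so its count is uncertain.

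Glycolysis genes fell in 6 of 22 and rose in 2, also when adjusted over the list alone (median -0.46, cameraPR adjusted p = 0.112). LDHA (-1.50), PKM (-1.42) and ENO1 (-1.28) fell, and the glucose transporter gene SLC2A1 (2.15) and hexokinase gene HK2 (1.44) rose, in the authors' deposited table. Vacuolar, lysosomal and autophagy genes rose in 8 of 38 and fell in 2, also when adjusted over the list alone (median 0.10, cameraPR adjusted p = 0.00701). LAMP3 (3.92), GAA (1.63) and CTSH (1.57) rose and CTSS (-1.77) and GLA (-1.25) fell in the authors' deposited table. At preset correlations of 0.05 and 0.1 this list was not called (cameraPR adjusted p = 0.0729 and 0.188). Ribosome biogenesis genes fell in 2 of 40, UTP20 (-1.57) and BOP1 (-1.01) in the authors' deposited table, and in 1 when adjusted over the list alone, with none rising (median -0.23, cameraPR adjusted p = 0.114).

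Of the 26 lists tested with cameraPR, 17 were called, 8 higher and 9 lower. An estimated correlation was not possible, because the table holds no values per library. At preset correlations of 0.05 and 0.1, 16 and 14 of the lists were called. Fisher's exact test found 19 combinations of a list and a direction enriched among the called genes. These took in Notch pathway genes among the rises (Benjamini-Hochberg adjusted p = 0.00273), and EGF receptor genes (0.0128) and glycolysis genes (0.0249) among the falls. Precision rose with depth: the median standard error in the authors' deposited table was 0.71 for genes with mean normalised counts of 10 to 20 and 0.29 for those of at least 5000. Against a null of 1.5-fold or less 730 genes were called, and FLG, KRT1, KRT10, OVOL1 and ITGB4 were not among them. The calls of HDAC1, ST14, DLL1 and BOP1 ended when fold changes were re-centred on the median of genes with a mean count of at least 100.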

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

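The prior undone and the length and GC correction were chosen only after the data were seen. Counts within 1.5 times of the 1988 calls came from thresholds of 0.01 and 0.1, a fold of at least 2, count minimums of 10 and 100, no filter, both re-centrings, and a fold of at least 2 with the prior undone, with 1392 to 2463 calls. Smaller counts came from a null of 1.5-fold or less (730 genes, 291 higher and 439 lower), the same null with the prior undone (835, 361 and 474), Bonferroni (702, 273 and 429), Benjamini-Yekutieli (1238, 524 and 714) and an empirical null (661, 249 and 412). Each of these asks for a larger statistic or change by construction. The empirical null divided the Wald statistics by a robust spread of 1.57, and whether that spread is noise or widespread small change was not tested.

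Between 14 and 18 lists were called under the alternatives, against 17, and 16 to 18 list and direction combinations were enriched, against 19. At a count minimum of 100 the melanocyte, fibroblast and appendage lists had too few members for a test. Glycolysis was called lower on ranks (adjusted p = 0.0212), with matched random lists (0.0306) and with the length and GC correction (0.012). EGF receptor ligands and feedback genes were called lower with matched random lists (0.00624) and with that correction (0.0168). Basal layer genes lost their call on fold changes (0.0529), and dermal fibroblast markers on ranks (0.0518). Vacuolar, lysosomal and autophagy genes lost theirs under 6 alternatives (0.0501 to 0.205). Ribosome biogenesis was called lower on ranks (0.00739). Direction turned for 3 lists that were not called under any setting. Tight and gap junctions turned on ranks (adjusted p = 0.824), with matched random lists (0.836) and with the length and GC correction (0.67). Histone methylation and acetylation enzymes turned at a count minimum of 100 (0.899) and with that correction (0.714), and calcium handling with matched random lists (0.969). The junction and calcium lists had positive mean log2 fold changes (0.22 and 0.11) and negative medians (-0.09 and -0.03). Matched random lists compare medians and cameraPR compares mean Wald statistics, so the turn of these lists with matched random lists goes with the summary used. The cause of the other turns was not tested.

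Of the 159 named genes with an adjusted p, 112 kept their side of the threshold against a null of 1.5-fold or less and 47 were no longer called. Re-centring by 0.05 ended 4 calls, of BOP1, DLL1, HDAC1 and ST14. No paired analysis was possible because the table has no values per library, which also left leaving out a replicate, a second count tool and an estimated correlation not run.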

Other observations

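The tests of immune cells and of IFNK below were chosen only after their results were seen, and the others were chosen before the values they measure were seen, for patterns already noticed in the data. ER chaperone genes, a group outside the fixed lists, were higher in the differentiated cultures. HSPA5, the main chaperone of the endoplasmic reticulum, had a log2 fold change of 2.70 (standard error 0.28) at a mean normalised count of 84169.6 in the authors' deposited table, and HSP90B1 (1.54), HERPUD1 (1.73), DNAJB9 (1.98) and SDF2L1 (1.78) also rose. Of the 6 genes of this group first seen, 5 were called higher and 1 was not called over all genes, with a log2 fold change of 0.76. DDIT3 (3.95), NUPR1 (3.12), PPP1R15A (1.73) and TRIB3 (1.07) rose in the authors' deposited table, while ATF3 (1.31), ATF4 (0.46) and ASNS (0.53) were not called. The standard error of ATF3 lay at the ceiling (0.75, log2 fold change 2.53 with the prior undone), so its missing call does not show that it was unchanged. ASNS and ATF4 share 83.0% and 37.5% of their 31-base words with transcripts of other genes in the reference, so their counts are uncertain.

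The fibronectin gene FN1 (-1.67, mean normalised count 88241) and the actin gene ACTB (-1.32, 47749.6) fell in the authors' deposited table. NCCRP1 rose by 3.99 on the log2 scale of the authors' deposited table. RPLP0P2, a ribosomal protein pseudogene, stood at 5.26 in the authors' deposited table, whereas its parent RPLP0 had 0.44 and was not called.

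For the fall of interferon-stimulated genes, the counts argue against a loss of immune cells from the cultures, since lineage-restricted immune markers summed to 0.0561% of the mean counts of the interferon-stimulated genes, and the most abundant, CD14, had a mean normalised count of 4.19 in the authors' deposited table. The fixed immune list came to 2.21% through CD68 (mean normalised count 336) and CD74 (19.3), which were left out of that sum because other cell types express them, and neither was called in the authors' deposited table (0.67 and -0.34). A trend with transcript length and GC content left the list median at -1.83 once removed. Lower expression of IFNK, the keratinocyte interferon, at -3.97 (DESeq2 adjusted p = 6e-22 in the authors' deposited table), may lie behind the fall, but IFNE was also counted (39.5, log2 fold change 0.09) among the 20 interferon genes listed, and with 2 groups the order of events cannot be told apart.

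Of 34 further ER chaperone genes 18 rose, 0 fell and 16 were not called, and their median Wald statistic stood at percentile 100 of 10000 matched random lists. Since these genes are of the same kind as those first seen, this describes the extent of the pattern, and an unfolded protein response as its cause stays open. A set of 26 measured ATF4 amino acid response genes stood at percentile 99.8, with 6 higher, 0 lower and 20 not called, and a median log2 fold change of 0.38. An ATF4 amino acid response may contribute, but these genes could also rise under an unfolded protein response, so the test does not tell them apart. Removing a trend with transcript length and GC content left the chaperone genes at percentile 100, which argues against that trend as the whole cause. Whether calcium itself or differentiation goes with the rise was not tested, since the design holds both together.

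Some well-counted differentiation genes had large standard errors. Of 9104 genes with a mean count of at least 100, 23 had a standard error at least 1.5 times the median of genes of similar count and change, among them IVL, SPRR1A, SCEL, SBSN, SLPI, FOSB, ATF3 and MKI67, and 13 of the 23 were not called. The median share of 31-base words in common with other genes was 0.0134%, against 0.181% for 204 control genes, which argues against shared reads as the general cause. LGALS7 (32.7%), SPRR1A (26.25%), SERPINB2 (24.4%) and MT1E (23.2%) shared more, so shared reads stay open for them. Libraries of a group at different extents of differentiation may account for the large standard errors: the median relative standard error of 57 other differentiation genes, pooled from 3 lists, stood at percentile 99.8 of matched random lists, at 1.02 times the typical value. Alone, none of the 3 lists passed (adjusted p = 0.275 for suprabasal keratins, 0.275 for barrier lipids and 0.0613 for kallikreins), whereas mitosis genes did (1.03 times, adjusted p = 0.0391), against 1.25 times for the cornified envelope list in which the pattern was noticed, and differences between cultures, donors or batches remain untested.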
